A study of Rattus norvegicus with 14 samples.

How the data were processed

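Total RNA of 7 rat lines, 1 µg per sample with 10 spiked-in viral transcripts, was labelled with Cy3 and hybridized to 14 Agilent one-colour arrays on 4 slides. Per the file headers the authors extracted spot values with Agilent Feature Extraction 10.7.3.1, which corrected background and spatial trends. The deposited scanner tables give the processed signal, the mean signal and the local background of each spot as an intensity, not scaled between arrays, and flags of 0 or 1 as other values. The deposited series table holds log2 values. When sorted they equalled the log2 processed signal of the same array, with a largest difference of 0, so that table was not scaled between arrays either.

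Processed signals were put on the log2 scale and the 75th percentile over the 43379 non-control spots of the array was subtracted. Spots marked as outliers by the scanner software were left out, 65 to 193 per array, and spots of one probe were averaged. Probe names were updated through a RefSeq gene table of a newer rat assembly, GRCr8, used for names only, in which 22007 of 41012 probes matched, and 19005 kept the name in the files. Positions are those of the files. A gene was kept if its probe was well above background on both arrays of at least 1 line, and the brightest probe stood for a gene. This left 24742 names, called genes below. Part of them are not gene symbols, so a gene may be counted under more than 1 name. Where a group was not above background on any array, a fold is given as a lower bound against the lowest signal called above background.

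Arrays A and B of a line were averaged before the fit, since the labels do not say whether they came from separate cultures. The 14 arrays made 3 blastocyst lines, 3 bone marrow lines and 1 mesenchymal line. The line means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Contrasts were blastocyst against bone marrow lines, the mean of both against the mesenchymal line, and each against it. Sex and strain were tested among the 6 stem cell lines with origin as a covariate. Lines of one origin were compared by an F-test over the arrays, whose replicates are arrays of one line. Fixed gene lists, 24 with measured members, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over lists and the 4 contrasts. The X inactivation list had no measured member.

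Named genes were, per contrast, the 12 largest differences in each direction among genes with a symbol that passed and whose line means did not overlap, all members of the list of key genes, and up to 4 members of each list. Only part of these is printed, chosen for length. Lists, comparisons, the rule and most alternatives were set before the data were examined. The alternatives were other background correction, normalization, filters, probe choice, block and covariate terms, a test against a fold of 1.5, and leaving out lines or arrays. Spike-in scaling, median centring, terms for the slide pair, fits within slides and the fits without single RMAPC-1 arrays were added after the data were seen.

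On simulated data made with the spread of the lines, the fit for blastocyst against bone marrow lines recovered 26.9% of genes changed by 1 on the log2 scale, 83.6% of those changed by 2 and 93.9% of those changed by 4, with 4 false calls. For the stem cell lines against the mesenchymal line these shares were 8.96%, 76.1% and 93.9%. In each simulation 67, 67 and 66 of 24742 genes were changed by these sizes, while 33.0% and 47.2% of genes passed in the data. The adjustment over genes then differs, so these shares do not give the recovery in the data. The mesenchymal line was simulated with the spread of the other lines. Treating the 14 arrays as replicates with line as a random block gave 52 false calls in the first comparison, so that fit is an alternative only. Figures were drawn with matplotlib 3.10.9.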

Results

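RNA of 7 rat cell lines was measured on 14 one-colour microarrays, with arrays A and B for each line. Fi1, Fi2 and Wk8 were derived from blastocysts, and CL19, 3C3 and RMAPC-1 from bone marrow. RClone-2, a mesenchymal line, served as the control. Wk8 came from a Wistar-Kyoto rat and the other lines from Fischer rats. Each array held 41012 distinct probes, and 61.6% to 67.9% of the probes were well above background. The 75th percentile of the processed signal was 745.7 to 891.5 on the blastocyst arrays, 558.9 to 660.1 on the bone marrow arrays, and 599.0 and 630.7 on the mesenchymal arrays. All values are log2 signals relative to that percentile of the same array, and the line was the unit of replication, so that the number of lines limits the precision.

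The mesenchymal line stood far from the 6 stem cell lines. The first principal component of the line means held 73.2% of the variance and parted RClone-2 from the rest. The second held 16.3% and parted blastocyst from bone marrow lines. Across genes, which are not independent replicates, stem cell and mesenchymal arrays correlated at 0.794 to 0.803. Blastocyst and bone marrow arrays correlated at 0.942 to 0.982. Arrays of different blastocyst lines reached 0.973 to 0.990 and those of different bone marrow lines 0.977 to 0.989. These ranges overlap, and Fi2 correlated more with the bone marrow line CL19 (0.978 to 0.982) than with the blastocyst line Wk8 (0.973 to 0.975).

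**Figure D1:**
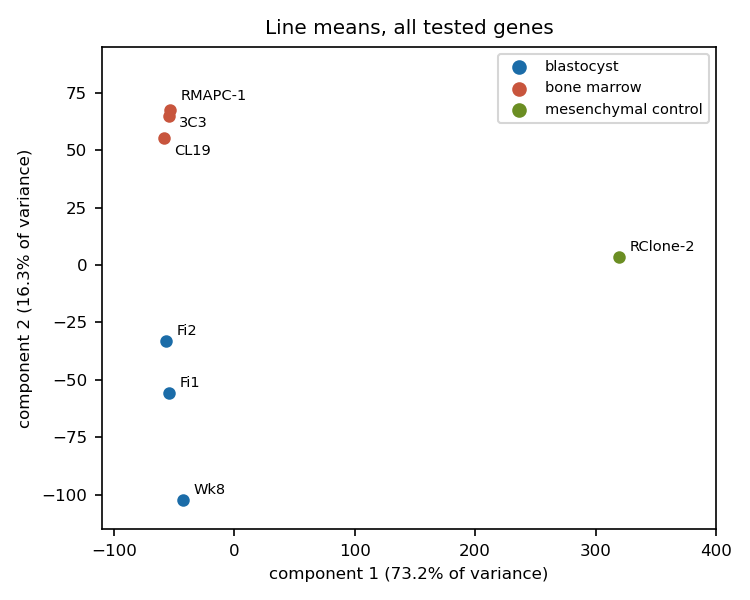
Line means of the tested genes on the first 2 principal components, 1 point per line, coloured by origin, with the share of variance on each axis. RClone-2 lies apart on component 1 (73.2%), and the blastocyst and bone marrow lines part on component 2 (16.3%).

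The first comparison asked how the stem cell lines differed from the mesenchymal line. Transcription factors of the primitive endoderm, the extraembryonic layer also called hypoblast, were far higher in the stem cell lines. Gata4 was 90.8-fold higher (log2 difference 6.51 ± 0.17, SE, 6 lines against 1), Gata6 222-fold (7.79 ± 0.17), Sox17 550-fold (9.10 ± 0.31) and Foxa2 308-fold (8.27 ± 0.20). Sox7 was at least 401-fold higher, because it did not rise above background in RClone-2. Pdgfra, a growth factor receptor, was 121-fold higher, and Lama1, a laminin chain of the basement membrane, 2180.2-fold. The pluripotency factor Pou5f1 was at least 210-fold higher and was above background on all 12 stem cell arrays. The epithelial adhesion genes Cdh1 and Epcam were at least 295-fold and 395-fold higher. Adjusted p-values of these genes lay between 1.8e-06 and 2.1e-04.

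Genes of the mesenchymal list mostly ran the other way. Col1a1 was 15.7-fold lower by its brightest probe (log2 difference -3.97 ± 0.15), with -5.86 by another probe above background on all arrays, and Thy1, a surface marker of mesenchymal cells, at least 33.0-fold lower in the stem cell lines. The chemokine Ccl2, the matrix protein Spp1, Thbs2 and the collagen gene Col5a2 were above background in RClone-2 alone, and were lower in the stem cell lines by factors of at least 10446, 6495, 9063 and 6394. Among genes with the largest positive differences, Rbpms was at least 924-fold, Lipg at least 603-fold and Fbxo2 at least 579-fold higher, while Sall4 was 2275-fold and Pth1r 2259.8-fold higher. The visceral endoderm genes Afp and Ttr were at least 4.87-fold and 3.88-fold higher, and Eomes at least 7.40-fold. Dab2 (log2 difference 1.88 ± 0.63, adjusted p = 0.0526), Hnf4a (-0.42 ± 0.15, adjusted p = 0.0674) and Cdx2 (-0.32 ± 0.34, adjusted p = 0.467) did not pass. Hnf4a and Cdx2 changed sign in other settings, and the other probe of Hnf4a gave 0.89 without passing.

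**Figure D2:**
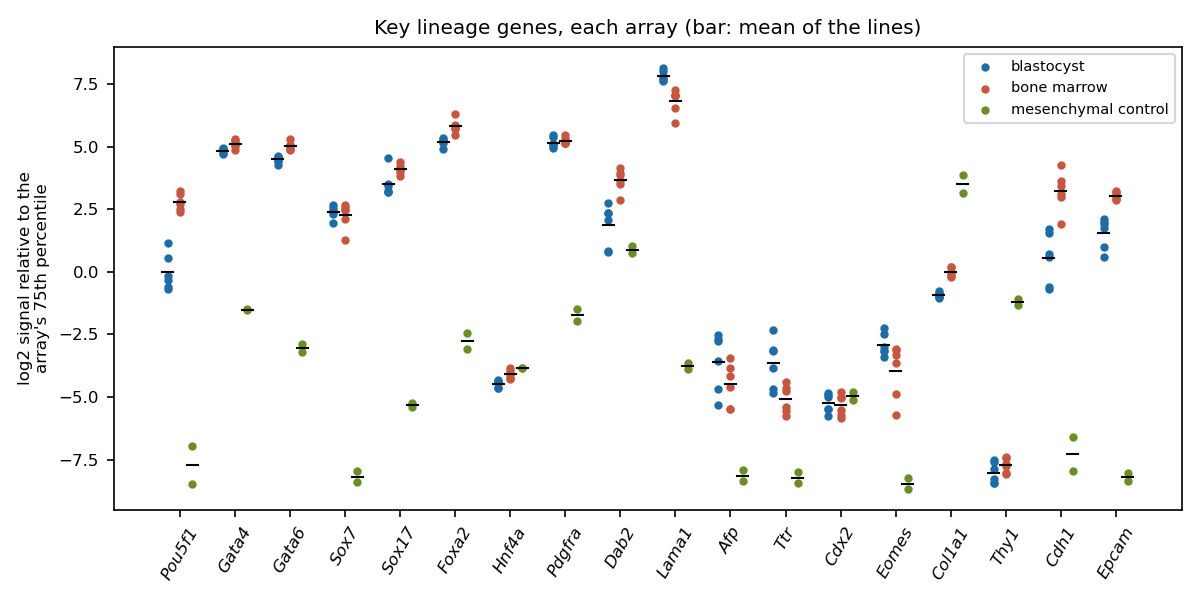
Log2 signal of 18 lineage genes relative to the 75th percentile of each array. Points are single arrays (6 blastocyst, 6 bone marrow, 2 mesenchymal) and bars the means of the lines. Gata4, Gata6, Sox17 and Foxa2 lay higher in both kinds of stem cell line than in RClone-2, and Col1a1 and Thy1 lower.

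Of 24742 genes tested with limma, 11683 passed, 6117 higher and 5566 lower in the stem cell lines, and 8444 of these differed over 2-fold. Of 25 measured primitive endoderm genes 21 rose and 0 fell. Of 19 epithelial genes 17 rose and 0 fell, with the keratins Krt18 1619-fold and Krt19 at least 466-fold higher. Of 17 pluripotency genes 13 rose and 1 fell, of 19 visceral endoderm genes 13 rose, among them Hhex, at least 206-fold higher, and 1 fell, and of 19 parietal endoderm genes 15 rose and 2 fell. Of 33 mesenchymal genes 26 fell and 1 rose. Of the 18 key genes 13 rose and 2 fell. The key gene Sox2 was not well above background on both arrays of any line, and Nanog had no probe of that name. The pluripotency list named 28 genes, so the 17 tested are a part of it. Esrrb, Fgf4 and Fgf5 were left out for the same reason as Sox2, and the rest for lack of a probe. Adjusted over the list alone, 23 primitive endoderm, 18 epithelial, 14 pluripotency, 15 visceral endoderm, 17 parietal endoderm, 29 mesenchymal and 17 key genes passed. These 7 lists shifted against the other genes by camera with a preset correlation (adjusted p from 2.1e-10 to 0.00189). With an estimated correlation none of the 24 lists passed, and the adjusted p of these 7 ranged from 0.0974 to 0.541. A single mesenchymal line stood for its group, and its spread was taken from the other lines.

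Taken by origin, the blastocyst lines differed from RClone-2 in 12061 genes (5520 higher, 6541 lower) and the bone marrow lines in 11445 (6626 higher, 4819 lower). Both had higher Pou5f1, at least 79.4-fold in blastocyst and at least 553-fold in bone marrow lines. Among the largest differences of the blastocyst lines were Cd200, Adgrf5 and Igfbp3, a binding protein of insulin-like growth factors, at least 757-fold, 755-fold and 786-fold higher. Among those of the bone marrow lines were the imprinted RNA gene H19 (4575-fold), Dnmt3l (4111-fold), a cofactor of DNA methylation, and Amn (3483-fold), part of an endocytic receptor. Ccl2 was lower by at least 12012-fold in blastocyst and 9085-fold in bone marrow lines. Of the 18 key genes, 13 rose and 3 fell in the blastocyst lines, and 14 rose and 2 fell in the bone marrow lines. Dab2 was 6.87-fold higher in bone marrow lines (adjusted p = 0.0183), while in blastocyst lines it did not pass (log2 difference 0.98, adjusted p = 0.273). Hnf4a was lower in the blastocyst lines (-0.63, adjusted p = 0.0230) and the call was lost without Fi1 or Fi2, at an adjusted p of up to 0.0528, and without the A or the B arrays (0.0875 and 0.0603). Its other probe gave 0.50 without passing (adjusted p = 0.520), so the direction depended on the probe. In bone marrow lines Hnf4a did not pass (-0.21, adjusted p = 0.336), nor did Cdx2 in either (-0.29 and -0.36). By camera 7 lists shifted in blastocyst and 8 in bone marrow lines, 0 of them with an estimated correlation. The eighth was the interferon response, with 10 of 19 genes lower and 4 higher in the bone marrow lines (adjusted p = 0.0412, and adjusted p = 0.642 with an estimated correlation). This call of the interferon response was lost by quantile normalization (0.0739), on unscaled values (0.0523), and without 3C3 (0.0520), RMAPC-1 (0.105), array A of RMAPC-1 (0.154) or all A arrays (0.212). That of the parietal endoderm genes (adjusted p = 0.0319) was lost without the B arrays (0.0823) and within slides 2 and 4 (0.0533). The antiviral gene Isg15 was 301-fold higher in the bone marrow lines. Psmb9 was 5.93-fold lower (-2.57), a call that was lost without array A of RMAPC-1 (-1.85, adjusted p = 0.147), without all A arrays (-1.76, 0.185) and without the B arrays (-3.37, 0.0591). With a term for the pair of slides, 6162 genes passed for blastocyst lines versus mesenchymal line and 10115 for bone marrow lines versus mesenchymal line, and within slides 2 and 4, which held 3C3, RMAPC-1 and RClone-2, 8663 passed.

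The next comparison set blastocyst against bone marrow lines. The blastocyst lines had higher Nid1, a basement membrane linker (16.1-fold, log2 difference 4.01 ± 0.45, SE, 3 lines against 3), Plat, the tissue plasminogen activator (9.48-fold, 3.24 ± 0.39), and the caveolin genes Cav1 (20.1-fold, 4.33 ± 0.42, and 3.06 and 2.84 by its other probes) and Cav2 (at least 7.89-fold). Pdlim3 was 31.3-fold, Pmp22 23.7-fold, Itga9, an integrin chain, 21.1-fold, and Adgrf5 19.6-fold higher. The bone marrow lines had higher Pou5f1, so that it was 6.97-fold lower in blastocyst lines (-2.80 ± 0.39, adjusted p = 0.00836). The germline and pluripotency gene Dppa3 was 18.3-fold lower (-4.19 ± 0.62), the transcription factor Runx1 20.4-fold lower and the cell polarity gene Crb3 44.3-fold lower. The receptor Fgfr2 was 51.5-fold lower by its brightest probe (-5.69), while another probe gave -2.72 and a further one -0.33, which did not pass (adjusted p = 0.0683). H19 was lower too (-4.25 ± 0.80).

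**Figure D3:**
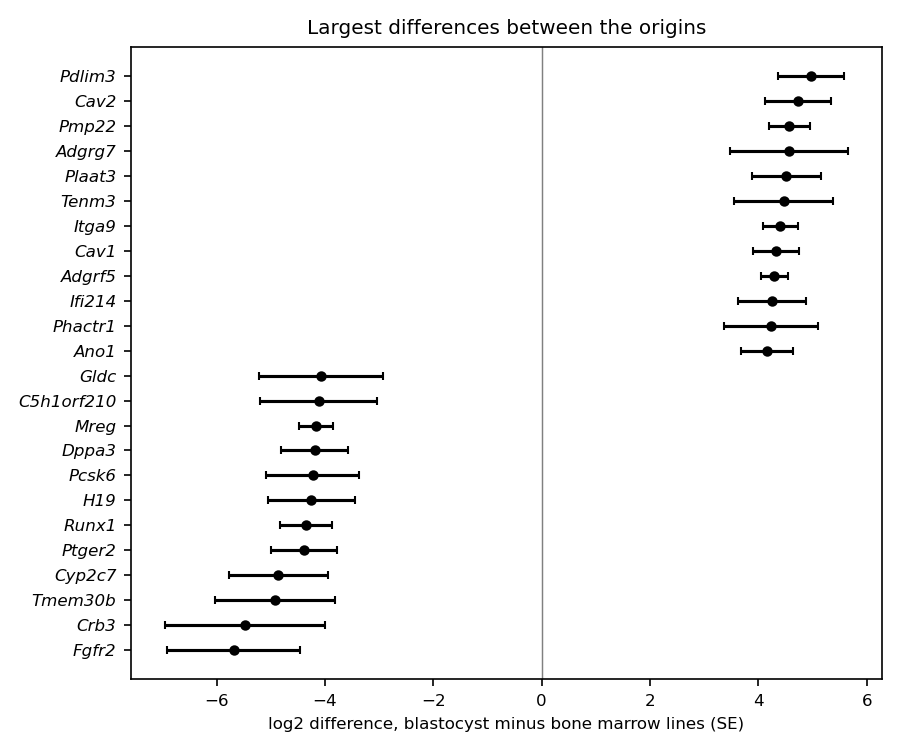
The 12 largest positive and 12 largest negative log2 differences, blastocyst minus bone marrow lines, with standard errors (3 lines against 3). They run from Fgfr2 at -5.69 to Pdlim3 at 4.97.

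Several primitive endoderm factors did not pass between the origins, while 4 of 25 genes of that list were higher and 8 lower in the blastocyst lines. Of all 24742 genes, 2044 were higher and 6109 lower. The list as a whole did not pass by camera (adjusted p = 0.980). Among its lower genes were Cited1 (-2.98, adjusted p = 0.00886) and Foxq1 (-3.22, adjusted p = 0.0262). The call of Cited1 was lost without the A arrays (0.0651). That of Foxq1 was lost without CL19, 3C3, RMAPC-1 or the B arrays (up to 0.0782). Gata4 (log2 difference -0.28 ± 0.13, adjusted p = 0.144), Sox7 (0.11 ± 0.22), Sox17 (-0.59 ± 0.24) and Pdgfra (-0.07 ± 0.12) did not pass, nor did Afp (0.91 ± 0.69), Ttr (1.42 ± 0.45), Cdx2 (0.08 ± 0.26), Eomes (1.06 ± 0.40) or Thy1. Gata4, Sox7, Pdgfra, Cdx2 and Thy1 changed sign in other settings. Gata6 (-0.54 ± 0.13), Foxa2 (-0.63 ± 0.15) and Hnf4a (-0.41 ± 0.12) passed with lower values in blastocyst lines by their brightest probes. The other probes of Gata6 gave 0.02 and -0.21 and that of Hnf4a -0.77, none of which passed, so the difference of Gata6 rests on 1 probe. Lama1 was 2.02-fold higher. Dab2 was 3.49-fold, Cdh1 6.36-fold and Epcam 2.79-fold lower. Col1a1 was lower by both probes above background on all arrays (-0.91 ± 0.11 and -0.46), while its remaining probe was at background on most stem cell arrays and was not used. The other probe of Sox17 gave 0.07. Hnf4a turned to 0.06 in the unscaled values.

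In the test of blastocyst lines versus bone marrow lines, 8153 genes passed, 2044 higher and 6109 lower in the blastocyst lines. Of the 8153, 3867 had a gene symbol, and 2836 differed over 2-fold, 1116 higher and 1720 lower. The median of all genes was -0.22, and the share of calls on the higher side moved with the scaling, from 25.1% to 39.7% by quantile normalization, 41.6% with the percentile over probes detected on all arrays, 82.6% unscaled and 12.4% by the spiked-in transcripts. Without RMAPC-1, whose arrays A and B differed from each other, 3097 genes passed, 4881 without its array A and 8383 without its array B. Without Fi1 3722 passed and without 3C3 3152.

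The 3 blastocyst lines and CL19 shared slides 1 and 3, and 3C3, RMAPC-1 and RClone-2 shared slides 2 and 4. With the slide as a block 3228 genes passed for blastocyst lines versus bone marrow lines. That fit took arrays as observations with line as a random block, the design that gave 52 false calls on simulated data. For the genes named in this comparison the blocked difference equalled that within slides 1 and 3. It therefore set the blastocyst lines against CL19 alone, and its calls do not rest on lines as replicates. With a term for the pair of slides at the level of line means limma called 0 (6500 at an unadjusted p under 0.05), and within slides 1 and 3, with CL19 alone for bone marrow, 0 (5248 unadjusted). Of the 55 genes named in this comparison that passed, 35 still passed with the slide as a block. Pou5f1, Nid1, Plat, Dppa3, Runx1, Fgfr2 and H19 were among them, and Crb3, Cdh1, Lama1, Gata6, Foxa2 and Hnf4a were not. With the block the differences of Crb3 (-5.57), Cdh1 (-2.66), Gata6 (-0.58) and Hnf4a (-0.42) stayed near those of the main fit. Those of Lama1 (0.67) and Foxa2 (-0.48) were smaller. Processing mattered too: of the 55, 19 lost their call with normexp background correction and 9 by quantile normalization. On unscaled values 10 lost theirs and 1 more changed sign. Without each line in turn, 29 of the 55 passed every time. All 55 kept their direction, which was largely fixed beforehand and tests little. The largest differences were chosen with line means that did not overlap, and the other genes had passed with all lines. Without Fi1, CL19, 3C3 or RMAPC-1 the calls of Crb3, Fgfr2 and Dab2 were lost (adjusted p up to 0.10, 0.0680 and 0.0973). H19 and Lama1 lost theirs without 3C3 or RMAPC-1 (up to 0.0546 and 0.0646), and Cdh1 and Epcam without CL19, 3C3 or RMAPC-1 (up to 0.0637 and 0.0715). Gata6 and Hnf4a lost theirs without any one of the 6 stem cell lines (up to 0.0828 and 0.117), and Foxa2 without any but CL19 (up to 0.0770). Without all A arrays the calls of Crb3, Fgfr2, Dab2, Epcam, Gata6, Foxa2 and Hnf4a were lost (up to 0.141), and without the B arrays those of Cdh1, Lama1, Gata6, Foxa2 and Hnf4a (up to 0.106). Array A of RMAPC-1 alone ended the calls of Crb3, Dab2, Gata6 and Hnf4a when left out (0.0519, 0.0525, 0.0530 and 0.0727).

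By gene list, 9 of 19 parietal endoderm genes were higher in the blastocyst lines and 1 was lower. Parietal endoderm lays down a thick basement membrane. Of 14 endothelial genes 7 were higher and 1 lower, among them Vwf (5.89-fold) and Flt1 (5.52-fold, log2 difference 2.46, and 1.26 by its other probe), a receptor of vascular growth factor. Pecam1 did not pass (1.60 ± 0.51, adjusted p = 0.0576). Of 17 pluripotency genes 11 were lower and 0 higher, with Dnmt3l 7.98-fold lower. The call of Dnmt3l was lost without Fi1, CL19, 3C3 or RMAPC-1 (adjusted p up to 0.128), array A of RMAPC-1 (0.0797), all A arrays (0.104) or the B arrays (0.0552), and that of Vwf with the slide as a block (0.0591). Adjusted over the list alone, 10 parietal endoderm, 10 endothelial and 14 pluripotency genes passed. Camera gave an adjusted p of 6.4e-05, 1.4e-04 and 0.00170 for these 3 lists, and an adjusted p of 0.512, 0.256 and 0.374 with an estimated correlation. The arrays of RMAPC-1 differed in these lists, with 8 of 14 endothelial genes over 2-fold higher on array B and 7 of 17 pluripotency genes on array A. Without array A the median of the endothelial list fell from 0.80 to 0.57 and the list still passed (adjusted p = 0.00435), and without RMAPC-1 that of the parietal endoderm list fell from 0.77 to 0.11, with an adjusted p of 2.4e-04.

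The other 5 lists that passed shifted upwards, each with few genes past the threshold. Of 20 imprinted genes 3 were higher and 1 lower, with Plagl1 16.0-fold higher, H19 lower, and Cdkn1c at 2.25 ± 0.72 (adjusted p = 0.0590), a value that array A of RMAPC-1 carried, since without it the difference was 1.24 and passed (adjusted p = 0.0186). Of 19 hypoxia genes 4 were higher and 1 lower, with Adm, a vasodilator peptide, 10.0-fold higher. Of 13 antigen presentation genes 3 were higher and 1 lower, with the peptide transporter Tap1 3.04-fold higher, a call lost without the A arrays (1.42, adjusted p = 0.0576). Of 19 interferon response genes 2 were higher, Tap1 and Irf9 (0.36 ± 0.11), and of 16 genes in the list of p53 targets 3 were higher. Among these was Cdkn2a (8.69-fold), a cell cycle inhibitor that acts upstream of p53, whose call was lost without the A arrays (2.79, adjusted p = 0.0518). Camera gave these 5 lists an adjusted p between 0.00170 and 0.0361, and an adjusted p between 0.192 and 0.642 with an estimated correlation. Adjusted over the list alone, 3 imprinted, 5 hypoxia, 4 antigen presentation, 1 interferon response and 3 p53 target genes passed. By fry, which tests a list against no change and not against the other genes, the imprinted list alone of these 5 passed (adjusted p = 0.0161), and the others did not (hypoxia and antigen presentation 0.0549, interferon response 0.209, p53 targets 0.430). On unscaled values imprinted genes (0.110), interferon response (0.0831), antigen presentation (0.0526) and p53 targets (0.0632) were lost. The p53 targets were also lost without Wk8 (0.177), RMAPC-1 (0.160), array B of RMAPC-1 (0.0590) or all A arrays (0.0894) and with normexp (0.0513). Antigen presentation was lost without array A of RMAPC-1 (0.0541), and hypoxia within slides 1 and 3 (0.0539). The arrays of RMAPC-1 differed in these lists too. Over 2-fold higher on array B were 9 of 19 interferon response, 9 of 20 imprinted and 6 of 13 antigen presentation genes. On array A these counts were 0, 2 and 1. Of 16 p53 targets 5 were over 2-fold higher on array A and 2 on array B, and of 19 hypoxia genes 0 and 2. Adm lost its call with the slide as a block (0.0936), at a log2 difference of 3.30 against 3.33 in the main fit. Irf9 lost its call with that block too (0.177, at 0.45 against 0.36). Its call was also lost without any one of the stem cell lines (up to 0.123), and without the A arrays (0.288), the B arrays (0.0882) or array A of RMAPC-1 (0.240). Of 25 primitive endoderm genes 4 were higher and 8 lower, and of 19 epithelial genes 1 was higher and 7 lower, and neither list passed by camera (adjusted p = 0.980 and 0.325), while fry called the epithelial list lower (adjusted p = 0.0191) and not the primitive endoderm list (0.0742).

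**Figure D4:**
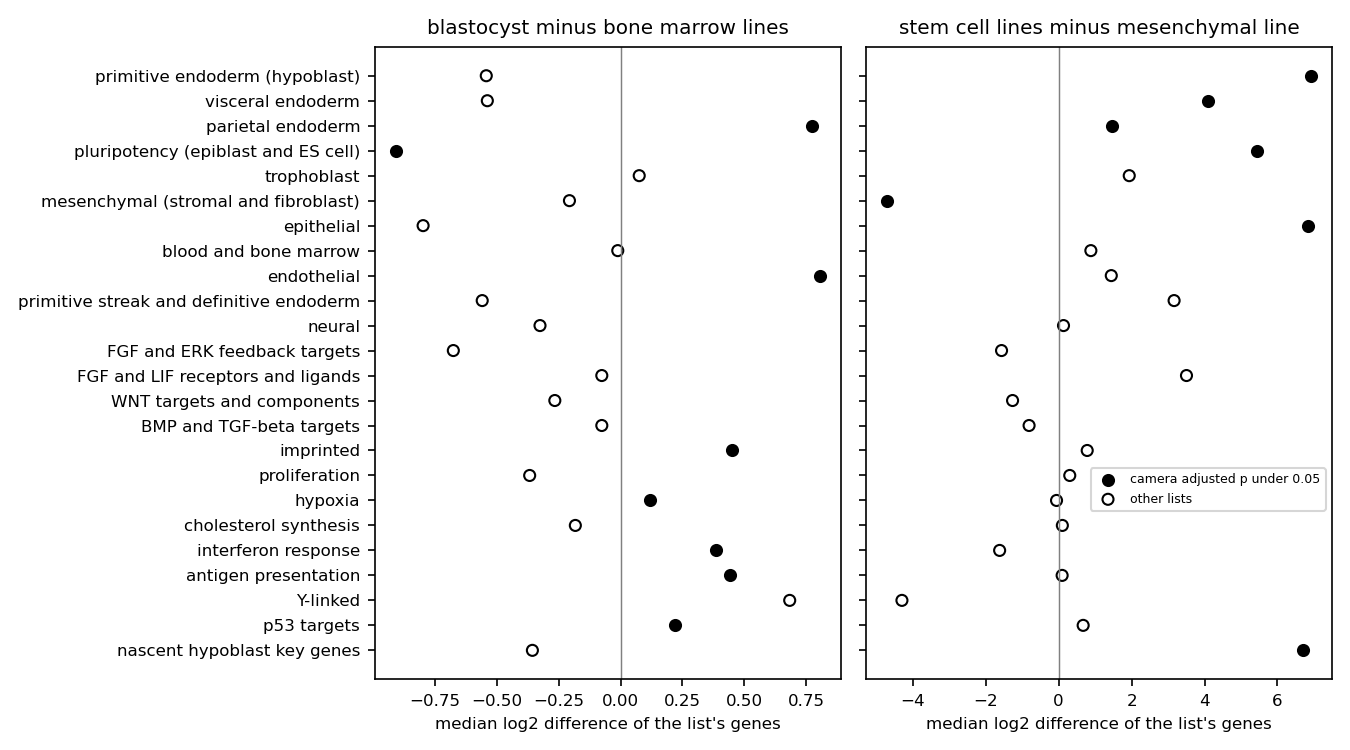
Median log2 difference of the measured genes of 24 gene lists, blastocyst minus bone marrow lines on the left and stem cell lines minus the mesenchymal line on the right. Filled points had a camera adjusted p under 0.05 with the preset correlation, 8 lists on the left and 7 on the right.

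Within the blastocyst lines Wk8 stood apart. Of 2108 genes that differed between these lines by a limma F-test over the arrays, Wk8 was the farthest from the middle line in 1621, Fi2 in 269 and Fi1 in 218. Fabp12, a fatty acid binding protein, and Cpb1, a carboxypeptidase, were above background in Wk8 and not in Fi1, with ranges of line means of 7.77 and 7.69. The lower ends of these ranges lay at background, so their sizes are not exact. Clmn was at background in Wk8, with a range of 7.03 that is not exact for the same reason. Of the differences between lines of one origin, bone marrow lines showed 189, with Cdh22 spanning 4.62. With another background correction 0 passed there (normexp, 803 at an unadjusted p under 0.05). For both origins the error of the F-test took in the A to B spread of all lines, RMAPC-1 included. The median range of line means over all genes was 0.40 in blastocyst and 0.36 in bone marrow lines. With origin as a covariate, 290 genes passed for Wistar-Kyoto line versus Fischer lines, 187 higher and 103 lower. Strain and line could not be told apart here, since Wk8 was the sole Wistar-Kyoto line. That count fell to 73 without Fi2, 85 without Fi1, 75 without CL19 and 133 without 3C3.

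Lines labelled female were set against those labelled male, with origin as a covariate. Limma called 0 of 24742 genes, with 725 at an unadjusted p under 0.05. The Y-linked genes contradicted some of these labels. Eif2s3y and Ddx3y were above background on both arrays of Fi1 and RClone-2, labelled male, and on none of Fi2, Wk8 and CL19, labelled female. In 3C3, labelled male, neither array showed them, with Eif2s3y at -8.23 and -8.01. In RMAPC-1, labelled male, array B showed them (Eif2s3y 2.09, Ddx3y -1.01) and array A did not (-7.05 and -7.31). Uty, the other Y-linked gene measured, did not part the labels. The comparison by sex therefore rests on labels that these genes did not bear out in 3 arrays. Arrays A and B of RMAPC-1 also differed over 4-fold in 530 genes at a mean log2 level above -4, against 8 to 38 genes in the other lines.

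**Figure D5:**
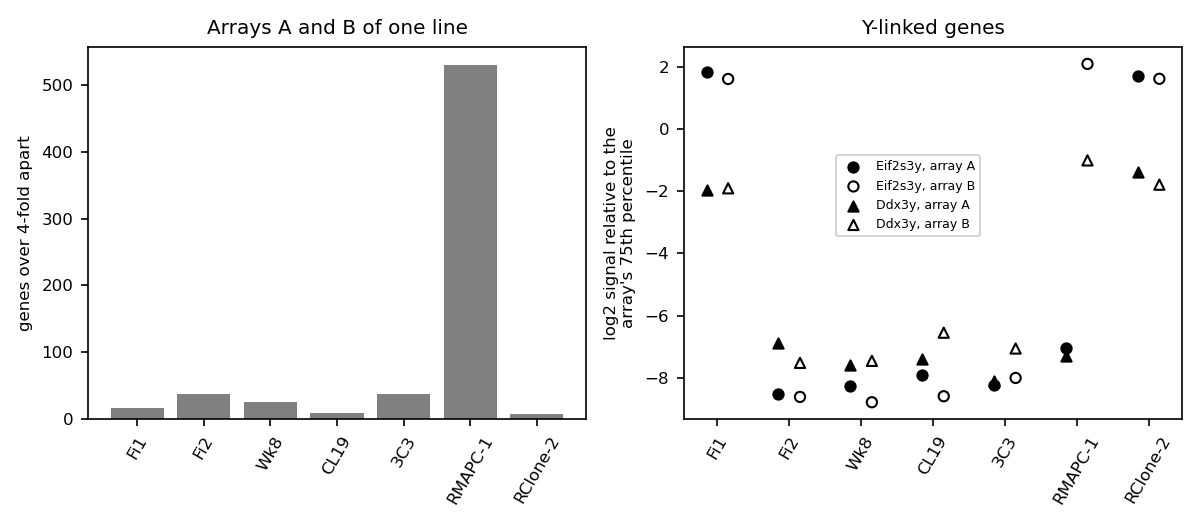
Left, number of genes over 4-fold apart between arrays A and B of each line, 530 in RMAPC-1. Right, log2 signal of the Y-linked genes Eif2s3y and Ddx3y relative to the 75th percentile on each array, with filled points for array A and open points for array B.

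The probes that gave these values lie, in build rn4 of the rat genome as the files give it, on chromosome 15 at 42473004 to 42473063 for Gata4, chromosome 18 at 2512492 to 2512551 for Gata6, chromosome 9 at 106973476 to 106973535 for Lama1, chromosome 16 at 49637181 to 49637240 for Pdlim3 and chromosome 1 at 189483073 to 189483132 for Fgfr2.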

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

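Tests of a mislabelled sample, of Y chromosome loss, of array detection and likeness in Wk8 and of the slide with lines not used to choose the genes were chosen after the result was seen. A bound for one test of the scaling was judged after its value was known, as said there. Of 48 groups of arrays, each 1 gene in the arrays of 1 origin, 3 had an array far from the others. If arrays were independent, 2.4 would be so by chance. Arrays A and B of a line are not independent, so that number does not judge the 3. Sox17 on array A of Wk8 was 4.54, against 3.18 to 3.49 on the other blastocyst arrays. Ddx3y on array B of RMAPC-1 was -1.01, against -8.10 to -6.55 on the other bone marrow arrays, and Eif2s3y was 2.09, against -8.59 to -7.05.

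The difference from the mesenchymal line itself differed between the origins at 9 of the 18 key genes, tested by limma as blastocyst minus bone marrow lines. The mesenchymal line cancels in this test, so the values repeat the comparison of the origins above. The log2 difference was -2.80 for Pou5f1, -0.54 for the brightest probe of Gata6, whose other probes did not pass, -0.63 for Foxa2, -0.41 for Hnf4a, -1.80 for Dab2, 1.01 for Lama1, -0.91 for Col1a1, -2.67 for Cdh1 and -1.48 for Epcam. A further 48 genes passed in opposite directions against the mesenchymal line, with the difference between origins past the threshold too, 44 of them higher in bone marrow lines. Those with a symbol were Kif21a, Il17ra and Plekhf1, higher in blastocyst lines, and Pacrgl, higher in bone marrow lines. For Kif21a the log2 differences were 1.62 and -0.84. The split of the 48 genes by direction was not tested under other scalings, and the direction of calls between the origins moved with the scaling.

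Arrays A and B labelled RMAPC-1 correlated at 0.971 across genes, below all 12 pairs of arrays of different bone marrow lines (0.977 to 0.989). Noise of one array is argued against, because over 3273 genes with a second probe the A minus B differences of the probes correlated at 0.654, against 0.213 to 0.469 in the other lines. Loss of the Y chromosome alone is argued against by the 530 genes over 4-fold apart. A wrong label on one array, or cultures that had diverged, may explain the pattern, and the test of the label could have come out the other way. Which array would be wrong stays open: array A was closer to the arrays of CL19 and 3C3, with correlations across genes of 0.983 to 0.987 against 0.977 to 0.979 for array B, and nearer to them at 315 of the 530 genes, while array B carried the Y-linked genes that the male label calls for, which 3C3, labelled male too, lacked.

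Blastocyst and bone marrow lines differed in 8153 genes, with 25.1% of calls on the higher side. A slide effect as the whole cause is argued against: over genes over 2-fold apart between 1 blastocyst line and the mean of 3C3 and RMAPC-1, another blastocyst line and CL19, which shared its slides, differed in the same direction in at least 86.0%, against at most 66.5% for pairs of blastocyst lines (a first test, at 98.8%, shared the blastocyst mean between both differences and decides nothing). Scaling stays open for the direction, as the unscaled share was 82.6%: median centring left 27.8%, past a bound set beforehand against the scaling, but that bound was wrong, a reason found after the value was seen, as the scaled medians of the origins differed by only -0.0154 and centring hardly changed the scaling. The spiked-in transcripts were brighter on the blastocyst arrays by 0.738, against 0.479 for the 75th percentile. Brighter labelling or scanning may thus contribute to the unscaled share. As the cause of the excess on the lower side it is argued against, since scaling by these transcripts left a still smaller share on the higher side. On slides 1 and 3 the transcripts gave 11.07 to 11.72 on the blastocyst arrays and 10.62 and 10.43 on those of CL19. Labelling that followed origin therefore could not be told apart from origin by the slide test. A biological difference of origin stays open too. The real split of the 6 lines was 1 of 10 splits to give 8153 genes, with 0 as the highest of the others, and 10 splits are too few for a share under 0.05.

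Wk8 stood apart from Fi1 and Fi2. A strain variant under single probes as the main cause is argued against, as the other probe moved the same way by over 0.5 times as much in 69.8% of the 53 genes that differed over 4-fold and had one. Detection is argued against: the Wk8 arrays (62.5% and 67.9% of probes above background) lay outside the range of the others in opposite directions, so that their mean difference of -0.0579 decides nothing, yet they correlated with each other across genes at 0.992 and with Fi1 and Fi2 arrays at 0.973 to 0.976. Strain, derivation and line stay open, because Wk8 was the one Wistar-Kyoto line, while Fi2, labelled female as Wk8 was, correlated across genes with Fi1 at 0.985 to 0.990 and with Wk8 at 0.973 to 0.975. For the comparison by sex the real split gave 0 genes, so each of 9 usable splits gave as many by construction (9 of 9, with 0 as the highest other), and the splits, too few for a share under 0.05, decide nothing.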

How the results depend on the processing

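Sizes of the counts, and between the origins the share of calls in each direction, depended on several choices, and the cause was not tested except where stated. With normexp background correction 1280 genes passed for blastocyst lines versus bone marrow lines, 5845 for stem cell lines versus mesenchymal line, 5444 for blastocyst lines versus mesenchymal line, 5763 for bone marrow lines versus mesenchymal line and 31 for Wistar-Kyoto line versus Fischer lines. A test against 1.5-fold, stricter by construction, left 594, 6612, 6785 and 6658 in the first 4. Between the origins 12584 passed with arrays as independent, 3228 with the slide as a block, 4521 with sex as a covariate, and by limma 0 with the slide pair at line means (6500 unadjusted) and 0 within slides 1 and 3 (5248), where fewer lines were compared. Leaving out lines or arrays gave 2585 to 8383. For blastocyst lines against the mesenchymal line the slide pair left 6162. The slide block gave 5 genes for female lines versus male lines. Strain gave 470 without a filter, 1349 with line as a random block, 1878 with arrays as independent, 1142 with a block for the array letter, 1180 with the slide block, and 73 to 324 without single lines or arrays. The A minus B differences of the lines correlated across genes at -0.24 to 0.18, over 0.1 in 2 of 21 pairs of lines, a hint from the data that the letters share little. Strain could not be fitted without Wk8, nor the mesenchymal contrasts without RClone-2.

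In the differences between lines of one origin, blastocyst lines gave 330 with normexp. In the differences between lines of one origin, bone marrow lines gave by limma 0 with normexp (803 unadjusted), 85 without a filter and 332 with a robust trend. Of the gene list shifts, blastocyst lines versus bone marrow lines had 8, and 5 on the unscaled values, of which 4 were among the 8. Fry, which tests a list against no change and not against the other genes, called 8, of which 4 were among these. With an estimated correlation camera called 0 in each of the 4 contrasts (2, 5, 5 and 5 unadjusted), and fry called 18 for stem cell lines, 17 for blastocyst lines and 16 for bone marrow lines against the mesenchymal line. Of the genes printed, those that reversed follow, and Hnf4a between the origins was the called one. Between the origins Gata4 was 0.019 by quantile normalization and 0.20 unscaled, Hnf4a 0.065 unscaled, Thy1 0.18 unscaled, and Pdgfra 0.25 by quantile normalization, 0.076 with the percentile over detected probes and 0.41 unscaled. Sox7 was -0.10 with the mean of probes. Without single lines or arrays Pdgfra ran from -0.15 to 0.023, Sox7 from -0.11 to 0.34 and Cdx2 from -0.11 to 0.26. Against the mesenchymal line, with the mean of probes Hnf4a was 0.23 for stem cell and 0.53 for bone marrow lines, and Cdx2 was 0.16 unscaled for blastocyst lines. Without lines or arrays Cdx2, stem cell lines versus mesenchymal line, ran from -0.65 to 0.0053, and Cdx2, bone marrow lines versus mesenchymal line, from -0.74 to 0.014. Signal near background limits genes such as Thy1, Afp and Cdx2.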

Other observations

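Some further gene groups held genes that passed, while none of these lists as a whole shifted by camera in the comparison given. Of 24 proliferation genes 7 were lower in blastocyst than in bone marrow lines and 0 higher. That lies near the share of all genes, 6109 of 24742 lower, and the list as a whole did not pass (camera, adjusted p = 0.176). Against the mesenchymal line, 8 of 14 feedback targets of the FGF pathway were lower in the stem cell lines and 3 higher, and 7 of 15 WNT genes were lower and 3 higher, without a shift of either list by camera. Wnt5a was 940-fold lower. The blood cell genes Gata1 and Coro1a were at least 83.7-fold and 34.4-fold higher in the stem cell lines, and 7 of 14 measured blood and bone marrow genes rose while 3 fell. The oxygen-regulated gene Egln3 was 66.0-fold higher.

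Array B labelled RMAPC-1 was at background for Car7 and Fmo5, which array A showed (log2 1.34 and 1.18), and showed Rgs13 and Wnt6 (-0.27 and 0.15), which array A did not (-8.02 and -7.47). The imprinted growth inhibitor Cdkn1c was 7.42 on array B and 1.39 on array A, against means of 6.87 in CL19 and 7.12 in 3C3. Of 14 endothelial genes 8 were over 2-fold higher on array B and 0 on array A, and of 17 pluripotency genes 7 were over 2-fold higher on array A and 1 on array B.

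Oas1b was -3.14 on array A of RMAPC-1 and -8.33 on array B, near Wk8 (-8.59), which prompted a test. At 113 genes, without Oas1b and Fabp12, that were all or none between Wk8 and both Fi1 and Fi2, array B of RMAPC-1 lay nearer to Wk8 at 33.6%, against 3.54% to 10.6% on the other bone marrow arrays. A hypothesis is that this array may hold cells of another strain background. Both arrays of RClone-2, a Fischer line, also lay nearer to Wk8, at 38.9% and 38.1%, so these genes do not mark strain alone and the state of a culture could give the same pattern.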
